A study of Mus musculus with 6 samples.

How the data were processed

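RNA was measured by sequencing in 6 libraries of mouse neural stem cells, 3 from wild type and 3 from Smchd1 null cultures. Per the labels' protocols, total RNA was extracted from cultured cells, and 1 µg per library went into the Illumina TruSeq RNA v2 kit, followed by single-read sequencing. That kit does not mark strand, so reads from a gene and from an overlapping antisense gene were not separable. The deposited values are raw counts, with an Entrez gene ID and a gene length beside each count. Per the submitters' processing notes, the tools were CASAVA 1.8.2, featureCounts, edgeR 3.8.2 and limma 3.22.0, and the genome build was mm10. The aligner, the gene annotation and the treatment of reads that match several genes are not given in the sources used here.

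All 6 deposited tables held the same 27179 gene IDs and lengths, and every deposited count was a whole number. Gene symbols and mm10 coordinates came from a RefSeq gene table of the GRCm38.p6 assembly, whose primary chromosomes are those of mm10. It matched 25275 IDs (93.0%), and the 1904 unmatched IDs were kept in the tests under their Entrez numbers. Total counts per library ran from 18608881 to 23253367. Intervals and floors based on counts pool the libraries of a group, so they cover counting error at most and leave out the spread between libraries. Reads were not tagged with molecular identifiers, so repeated reads of the same molecule could not be told apart.

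Groups were taken from the sample titles, which also number the replicates 1 to 3. The series summary speaks of cell lines, and nothing in the labels says that the replicates came from separate animals or derivations. The p-values then measure only the spread between these samples, which may be technical. Averaged over genes, every pair of libraries within a group differed by more than sampling noise, with mean chi-square values per gene of at least 7.79. A few large records can raise such a mean, so it does not show that most genes differed. The sample names in the labels carry the numbers 113 and 114 for wild type replicates 1 and 2, and 11 to 14 for the 3 null libraries and wild type replicate 3.

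Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, which kept 14207 genes, scaled by TMM, and fitted with a robust quasi-likelihood model that had genotype as its only term. Effective depth was 25.8, 23.5 and 10.1 M in wild type replicates 1 to 3 and 21.3, 21.3 and 22.4 M in null replicates 1 to 3. The two-sided quasi-likelihood F-test was adjusted by the Benjamini-Hochberg method over the tested genes, at an adjusted p threshold of 0.05. Standard errors of log2 fold changes were obtained from the fold change and its F statistic. CPM values are counts divided by the TMM-scaled library size in M counts. Fold changes were computed as null minus wild type on the log2 scale.

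A total of 30 gene lists was fixed before the data were examined. They cover clustered and other protocadherins, imprinted and Hox genes, markers of neural stem cells, neurons, astrocytes, oligodendrocytes, microglia, vessels, fibroblasts and red cells, and regional patterning genes. They also cover cell cycle phases, interferon, p53, Wnt and immediate early genes, matrix genes, germline genes, chromatin silencing regulators, cohesin and condensin genes, Y-linked genes, and olfactory, vomeronasal and Rhox families. The 26 lists with at least 3 tested members were tested with camera from limma 3.58.1 at an inter-gene correlation of 0.01. Camera was repeated with an estimated correlation, and fry was run as well. Camera was also run with the genes of each chromosome as a set. Pairs of neighbouring tested genes called in the same direction were counted and compared with 10000 random placements of the calls within 5 classes of expression.

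Named genes followed a rule also fixed before the data were examined. It takes Smchd1, then the 8 largest rises and the 8 largest falls among called genes with an average log2 CPM of at least 1, separate groups and no predicted or clone name. It adds the 4 members with the smallest p of each protocadherin cluster and of the imprinted and Hox lists, the 2 with the smallest p of each other list, and 5 sex checks. Not every gene the rule takes is printed. Other genes named in the text were chosen after their values were seen.

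Alternatives were DESeq2 1.42.0, limma-voom with and without sample quality weights, fits without robust moderation, 2 other scalings, no filter and a stricter filter. Libraries were also thinned to equal totals, the replicate number was added as a block, the range of sample-name numbers was added as a term, and each library was left out in turn. After the data had been seen, 3 further alternatives were added: leaving out genes above 1% of any library, the same with thinning, and keeping only the libraries named 11 to 14. In data simulated at the depths of these libraries, with 14207 genes of which 200 were changed, the edgeR test recovered 82% of genes changed 2-fold and 97% of those changed 4-fold. False calls made up 10.5% of its calls. With the sample-name term the test recovered 64% and 91%. The changed genes were drawn only from those with a mean above 1 CPM, and the simulation held no split by sample name. These shares therefore do not cover weaker genes or libraries with such a split. Figures were drawn with matplotlib 3.10.9.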

Results

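Neural stem cells were derived from brains of male mid-gestation mouse embryos, of the strain labelled C57BL/6 x FVB/N, and were grown with EGF and bFGF, each at 20 ng/ml. Gene expression was measured in 3 wild type libraries and in 3 libraries homozygous for MommeD1, a nonsense allele of Smchd1 labelled as null. Smchd1 encodes a chromatin protein related to the SMC family that is needed for silencing on the inactive X chromosome and at several autosomal gene clusters. The comparison asked which genes change their expression when Smchd1 is lost.

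The wild type libraries held 23253367, 20498667 and 19504879 counts for replicates 1, 2 and 3, and the null libraries held 18608881, 18848785 and 19137666. Wild type replicate 3 differed from the rest in composition. A single record, Entrez gene 100861531, for which the gene table used here gave no symbol, took 44.6% of its counts, against 2.11% to 5.90% in the other libraries. The 6 records above 1% of any library took 58.3% of its counts, against 5.84% to 11.7% elsewhere. After TMM scaling its effective depth was 10.1 M counts, against 21.3 to 25.8 M counts for the others.

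**Figure D1:**
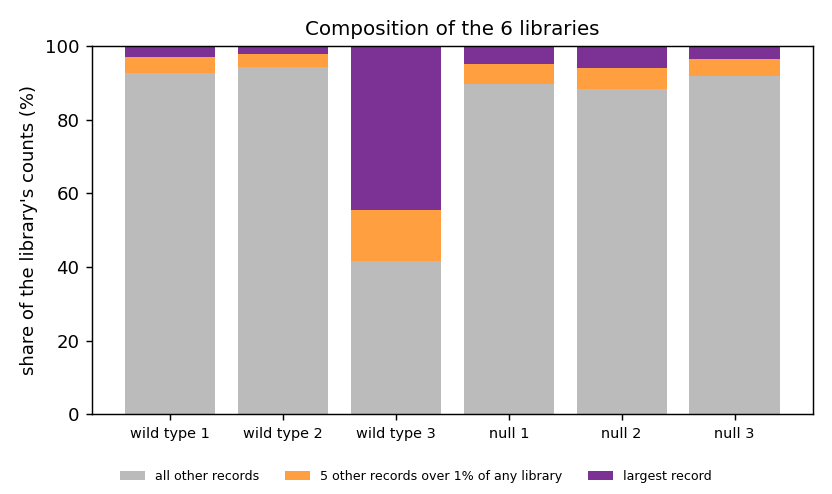
Share of each library's counts, in percent, taken by the largest record, by the 5 other records that exceeded 1% of any library, and by all other records. The largest record took 44.6% of wild type replicate 3 and at most 5.90% of any other library.

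The male label was matched by every library. Xist, the long noncoding RNA of the inactive X chromosome, had between 0 and 14 counts per library. The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty were expressed in all 6 libraries, at 39.5 CPM or more, and Ddx3y stood at 97.2 ± 11.9 CPM in wild type and 84.8 ± 5.47 CPM in null (mean ± SD, n = 3).

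Smchd1 (Entrez 74355, chromosome 17, 71344489 to 71475366, mm10) fell 8.55-fold, from 254 ± 20.0 CPM in wild type to 29.7 ± 1.68 CPM in null (mean ± SD, n = 3). Its log2 fold change was -3.10 ± 0.08 (SE), with an adjusted p of 1.09e-06 from the edgeR quasi-likelihood test. Each null library lay between 27.9 and 31.1 CPM, and the wild type libraries lay at 271, 260 and 232 CPM.

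Clustered protocadherin genes on chromosome 18 were the largest of the fixed gene groups among those that rose without Smchd1. Of 14207 genes tested, 72 rose and 10 fell. Of the 72, 26 (36.1%) were clustered protocadherins, which encode cell adhesion proteins of neurons. The others included the zinc finger genes Zfp992, Zfp993, Zfp991, Zfp979 and Zfp976. The median log2 fold change of the genes that rose was 2.27, and that of the genes that fell was -0.55. At an unadjusted p under 0.05 the edgeR test counted 2642 genes. All 82 called genes had groups that did not overlap, as had 22.0% of all tested genes, where chance gives 10%.

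The count of called genes depended on wild type replicate 3 and on the sample-name numbers. Without wild type replicate 3 the test called 5676 genes, 2857 higher and 2819 lower in null, against 39 and 45 without wild type replicate 1 or 2, and 30, 43 and 34 without null replicate 1, 2 or 3. With the range of sample names as a term, a fit that rests on wild type replicate 3 as the only wild type library named among 11 to 14, 77 genes rose and 109 fell. That fit kept 49 of the 72 rises and 6 of the 10 falls, and among the libraries named 11 to 14 alone 126 genes rose and 250 fell.

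**Figure D2:**
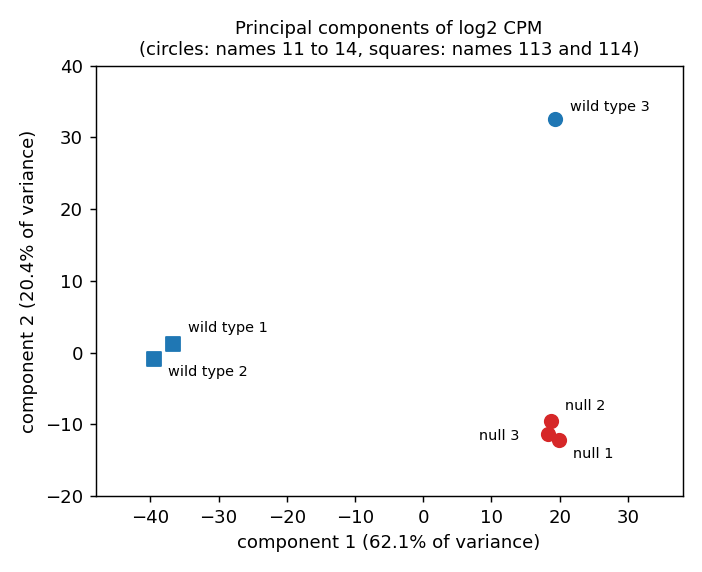
The 6 libraries on the first and second principal components of log2 CPM (arbitrary units), which held 62.1% and 20.4% of the variance. Wild type replicate 3 (19.3) lay with the null libraries (18.2 to 19.9) on component 1, apart from wild type replicates 1 (-36.6) and 2 (-39.5).

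Most alpha protocadherin genes were barely detected in wild type cells and higher in null cells. Of the 13 tested, 9 rose and 0 fell, and adjusted over the list alone 11 rose. Pcdha6 rose from 0.145 ± 0.089 to 4.68 ± 0.96 CPM (mean ± SD, n = 3), a log2 fold change of 5.05 ± 0.39 (SE) with an adjusted p of 0.000891. Pcdha8 rose by a log2 fold change of 4.43 ± 0.36 (adjusted p = 0.00106), Pcdha7 by 4.48 ± 0.53, Pcdha9 by 3.14 ± 0.39 and Pcdha10 by 2.67 ± 0.28 (adjusted p = 0.00346). The sample-name term lowered these to 3.72 for Pcdha8, 3.13 for Pcdha7 and 2.06 for Pcdha9, with 4.52 for Pcdha6 and 2.44 for Pcdha10, while Pcdha7 stood at 5.10 without wild type replicate 3. Pcdha5 had 3 counts over the wild type libraries, and the ratio of its pooled counts, scaled by library size, was 58.7 between null and wild type, with a 95% exact binomial interval of 19.8 to 287. Pcdha1 had 0 counts in wild type. Against a floor of 3 counts over the wild type group its ratio was 37.7, and the exact binomial 95% interval of its ratio starts at 30.2. Pcdha12 and Pcdhac2, near the end of the cluster, did not pass (log2 fold changes 0.54 ± 0.41 and -0.30 ± 0.49). Pcdhac2 had 12.01 CPM in wild type replicate 3 against 3.95 and 3.24 in replicates 1 and 2, and it fell once the sample-name term was added (log2 fold change -1.31, adjusted p = 0.00271).

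Beta protocadherin genes, single-exon genes just downstream, showed the same direction. Of 22 tested, 17 rose and 0 fell, and adjusted over the list alone 20 rose. Pcdhb22 rose from 11.2 ± 1.1 to 32.1 ± 0.66 CPM (log2 fold change 1.53 ± 0.09, adjusted p = 0.00029), and Pcdhb10 from 1.95 ± 0.99 to 14.3 ± 0.81 CPM (3.02 ± 0.26, adjusted p = 0.0014). Pcdhb4 (3.38 ± 0.22), Pcdhb2 (3.56 ± 0.32), Pcdhb3 (3.35 ± 0.28), Pcdhb5 (2.49 ± 0.19) and Pcdhb11 (3.60 ± 0.44) also rose. Sizes under the sample-name term were 2.21 for Pcdhb10, 2.48 for Pcdhb2, 2.64 for Pcdhb3 and 2.45 for Pcdhb11, with 3.37 for Pcdhb4, 2.17 for Pcdhb5 and 1.36 for Pcdhb22. Pcdhb11 had 6.55 CPM in wild type replicate 3 against 2.13 and 1.66 in replicates 1 and 2, and its log2 fold change was 4.22 without wild type replicate 3. Pcdhb15 and Pcdhb17 did not pass, at log2 fold changes of 0.24 ± 0.30 and 0.23 ± 0.17.

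Camera gave adjusted p values of 7.55e-53 for the alpha and 4.4e-89 for the beta list. Both had an adjusted p = 0.0958 with an estimated correlation, while fry gave adjusted p values of 0.046 and 0.0289. Under the sample-name term 7 alpha genes rose and 1 fell, and 14 beta genes rose. There the alpha list had an adjusted p = 0.556 with an estimated correlation, and the beta list passed, with an adjusted p = 0.0419 with an estimated correlation. Pcdha7 lost its call with the replicate block (adjusted p = 0.0544), without wild type replicate 1 (adjusted p = 0.0747) and without null replicate 1 (0.0722), 2 (0.0706) or 3 (0.0839). Pcdha9 did so without the same libraries (adjusted p = 0.0975, then 0.0617, 0.0725 and 0.0904). Pcdhb11 did so without wild type replicate 1 (adjusted p = 0.223) or 2 (0.107), or null replicate 1 (0.126), 2 (0.152) or 3 (0.153). The alpha genes share their last exons, so a count separates them only where the reads lie in their own first exons, and beta genes have similar sequences between which reads could be split.

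**Figure D3:**
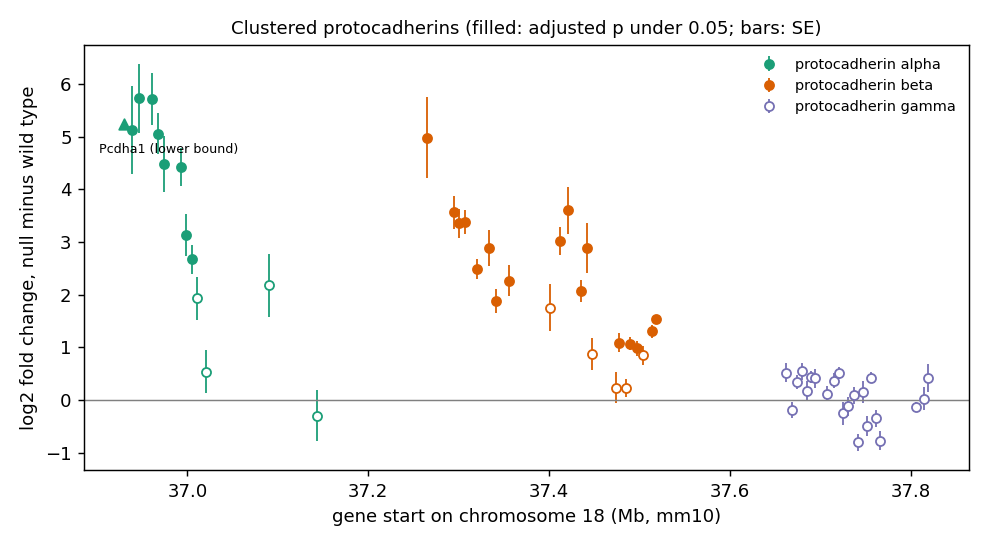
Log2 fold change between null and wild type (y axis) against gene start on chromosome 18 (x axis, Mb, mm10). Tested alpha, beta and gamma protocadherin genes are shown, with SE as bars and filled symbols for an adjusted p under 0.05. A triangle, marked as a lower bound, shows the ratio of Pcdha1 against a floor of 3 counts. In the alpha cluster 9 of 13 genes rose, in the beta cluster 17 of 22, and in the gamma cluster 0 of 22.

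In the gamma cluster, the next one along the chromosome, 0 of 22 tested genes passed the edgeR test. The limma-voom test also called 0, DESeq2 called 1, limma-voom with sample quality weights called 11, and 10 had an unadjusted p under 0.05. Adjusted over the list alone, 4 rose and 2 fell, and without wild type replicate 3 edgeR called 9 higher and 3 lower. The smallest p values belonged to Pcdhgb6 (log2 fold change -0.80 ± 0.16, adjusted p = 0.0886), Pcdhgb4 (0.51 ± 0.12), Pcdhga12 (-0.77 ± 0.18) and Pcdhga11 (0.42 ± 0.10). Camera, which tests for a shared direction, gave this list an adjusted p of 0.481. The mixed fry test, which lets members move either way, gave it an adjusted p of 0.00158.

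Among protocadherins outside the clusters, Pcdh7 rose from 48.4 ± 4.79 to 79.6 ± 7.49 CPM (log2 fold change 0.72 ± 0.10, adjusted p = 0.0138), 1 of 11 tested. Pcdh19 stood at 0.47 ± 0.16 (adjusted p = 0.209). In this list 9 genes were called higher and 1 lower without wild type replicate 3. Camera gave the list a higher direction with an adjusted p of 0.000558, and an adjusted p = 0.628 with an estimated correlation. Adding the sample-name term gave a camera adjusted p of 0.806. Pcdh7 lost its call without wild type replicate 1 (adjusted p = 0.104) or 2 (0.069), or null replicate 1 (0.133) or 3 (0.127).

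Of 59 tested imprinted genes, 3 rose and 0 fell, and adjusted over the list alone 3 rose and 4 fell. Leaving out wild type replicate 3 gave 16 calls higher and 16 lower. The 3 that rose are paternally expressed neighbours in the Prader-Willi region of chromosome 7. Ndn, a MAGE family gene of neurons, rose from 74.9 ± 3.71 to 148.6 ± 5.59 CPM (log2 fold change 0.99 ± 0.06, adjusted p = 0.000405). Peg12 rose from 148 ± 17.4 to 279.7 ± 8.86 CPM (0.91 ± 0.09, adjusted p = 0.00281), and Mkrn3, a ubiquitin ligase gene, from 10.3 ± 1.23 to 20.3 ± 0.49 CPM (0.96 ± 0.11, adjusted p = 0.00517). All 3 also rose with the sample-name term, and Mkrn3 lost its call only without null replicate 1 (adjusted p = 0.0617) or 3 (0.0606). Magel2 and Snrpn in the same region did not pass (0.79 ± 0.31 and 0.99 ± 0.29). Peg10, a retrotransposon-derived gene on chromosome 6, had a log2 fold change of -0.77 ± 0.15 (adjusted p = 0.0961). The list as a whole had a camera adjusted p of 0.383 for a shared direction. The mixed fry test, which lets members move either way, gave it an adjusted p of 0.00191. None of the 39 Hox genes was abundant enough to be tested, and the highest mean among them was 0.286 CPM.

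**Figure D4:**
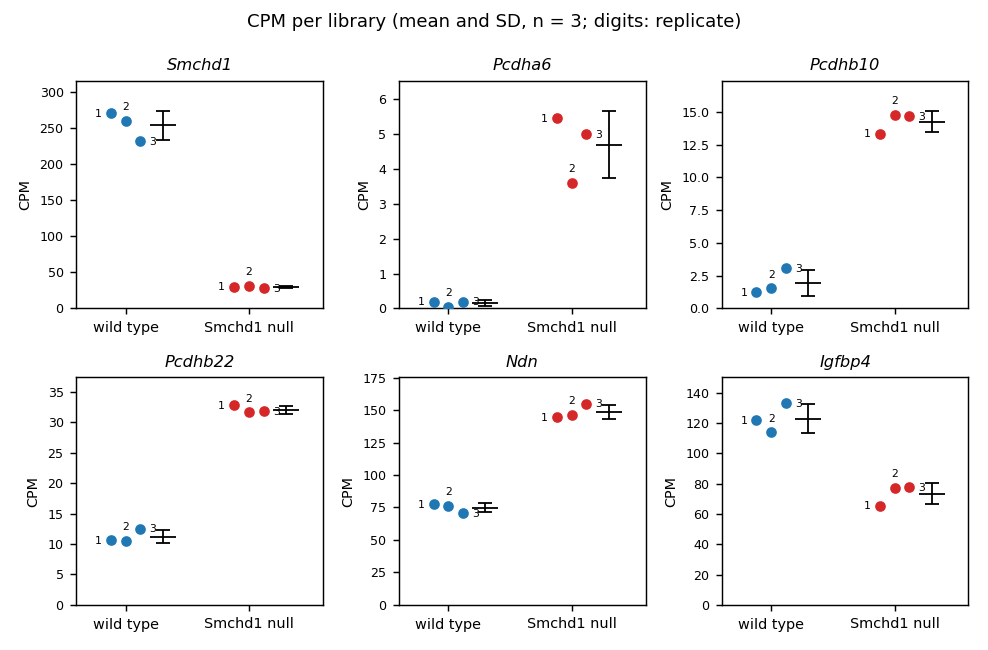
CPM of 6 genes in each library (points, numbered by replicate) with the mean and SD of each group (n = 3). Smchd1 and Igfbp4 were lower in all null libraries than in any wild type library, and Pcdha6, Pcdhb10, Pcdhb22 and Ndn were higher.

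The genes that fell changed little next to Smchd1, which was the only one of the 10 to fall more than 2-fold. Igfbp4, an insulin-like growth factor binding protein, fell from 123 ± 9.69 to 73.4 ± 6.99 CPM (log2 fold change -0.74 ± 0.09, adjusted p = 0.00758). Blvrb, a biliverdin reductase, fell with a log2 fold change of -0.70 ± 0.12, and Ccng2, a cyclin, with -0.62 ± 0.10. Tshz2, a zinc finger transcription factor gene, fell with -0.60 ± 0.10, and Bnip3l, a mitophagy receptor, with -0.51 ± 0.08 (adjusted p = 0.0353). Eif1, a translation initiation factor, and Rrbp1, a ribosome-binding protein of the endoplasmic reticulum, fell with -0.49 ± 0.07 and -0.44 ± 0.07. Blvrb, Ccng2, Tshz2 and Bnip3l did not pass with the sample-name term or with the replicate block. Eif1 (adjusted p = 0.0736) and Rrbp1 (adjusted p = 0.0742) lost their calls with the block as well. Igfbp4 lost its call without null replicate 1 (adjusted p = 0.0556) or 3 (0.0612). Blvrb, Tshz2, Bnip3l, Eif1 and Rrbp1 lost theirs without any 1 of wild type replicates 1 and 2 and null replicates 1, 2 and 3 (adjusted p from 0.0719 for Eif1 to 0.306 for Rrbp1), and Ccng2 without any of these except null replicate 2 (0.166 to 0.28).

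Neural stem cell markers were expressed in both groups, and no call was made among them. Nestin (Nes) stood at 1286 ± 70.2 CPM in wild type and 1184 ± 35.8 CPM in null, and Sox2 at 265 ± 17.7 and 278 ± 0.21 CPM. None of the 29 tested markers passed with edgeR or limma-voom, DESeq2 called 2 and limma-voom with quality weights 16, and 5 had an unadjusted p under 0.05. Without wild type replicate 3 edgeR called 7 higher and 10 lower, and with the sample-name term 2 lower. The smallest p values were those of Hes1 (log2 fold change -0.39 ± 0.10, adjusted p = 0.137) and Gli3 (24.1 ± 9.06 CPM in wild type and 12.3 ± 0.85 CPM in null, adjusted p = 0.165).

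Among neuronal markers Nefl, the light neurofilament subunit, rose from 0.72 ± 0.18 to 2.56 ± 0.52 CPM (log2 fold change 1.89 ± 0.28, adjusted p = 0.0228), 1 of 17 tested. Adjusted over the list alone 3 rose. Nefm, the medium subunit, stood at 0.71 ± 0.17 (adjusted p = 0.12). Camera placed the neuronal list higher in null (adjusted p = 0.0185), with an adjusted p = 0.628 with an estimated correlation. Nefl did not pass with the sample-name term (adjusted p = 0.137), nor did the list (adjusted p = 0.806). Nefl did not pass with the replicate block either (adjusted p = 0.0742). Nefl lost its call without wild type replicate 1 (adjusted p = 0.159) or 2 (0.121), or null replicate 1 (0.167) or 3 (0.174), and the list without wild type replicate 2 (0.0805) or without a filter (0.123). Among neuronal genes 10 were called higher and 4 lower without wild type replicate 3.

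For 3 more lists camera passed the threshold although no member was called. Oligodendrocyte lineage genes lay higher in null (adjusted p = 0.0239), for example Nkx2-2 (log2 fold change 0.60 ± 0.21) and Cldn11 (1.16 ± 0.54). S phase genes such as Cdc45 (-0.28 ± 0.09) and Uhrf1 (-0.25 ± 0.09) lay lower (adjusted p = 0.0318), as did cohesin, condensin and CTCF genes such as Smc1a (-0.24 ± 0.07) and Ncaph2 (-0.19 ± 0.06; adjusted p = 0.0185). With an estimated correlation these 3 lists had an adjusted p = 0.899, an adjusted p = 0.905 and an adjusted p = 0.899. Leaving out wild type replicate 1 gave 0.161, 0.454 and 0.0931, and leaving out wild type replicate 2 gave 0.132, 0.0805 and 0.0805. The oligodendrocyte list also lost its call without null replicate 3 (0.0592), and the other 2 without null replicate 2 (0.256 and 0.0515). The S phase list also lost it without the genes above 1% of a library and with thinning (0.061). Without wild type replicate 3 edgeR called 13 oligodendrocyte genes higher, 1 S phase gene higher and 16 lower, and 14 cohesin, condensin and CTCF genes lower. The limma-voom test called 0 genes in these lists, DESeq2 0, 0 and 1, and limma-voom with quality weights 12, 16 and 11, and 1, 2 and 4 genes had an unadjusted p under 0.05. All 3 directions turned with the sample-name term, where oligodendrocyte genes lay lower in null (adjusted p = 0.00204, but adjusted p = 0.556 with an estimated correlation) and S phase genes (adjusted p = 0.147) and cohesin genes (adjusted p = 0.569) lay higher. Pdgfra, a receptor of oligodendrocyte precursors, showed the split, with 67.6 ± 86.4 CPM over the wild type libraries and 126 ± 12.6 CPM in null.

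Among the remaining fixed lists no gene passed the edgeR test. Lrif1, which encodes a protein that binds SMCHD1 at chromatin, came closest, at 9.45 ± 1.25 CPM in wild type and 15.0 ± 0.50 CPM in null (log2 fold change 0.68 ± 0.12, adjusted p = 0.0505). It did not pass with the sample-name term (0.49, adjusted p = 0.17). It passed under 7 of the 20 alternatives, among them leaving out wild type replicate 3 (0.77, adjusted p = 2.53e-05). Rnf2, a Polycomb ubiquitin ligase gene on the same list of silencing regulators, stood at -0.30 ± 0.08. Matrix genes included Mmp2 (-0.55 ± 0.11) and Lamb2 (-0.60 ± 0.12), and astrocyte markers included Glul (-0.46 ± 0.10) and Gja1 (-0.68 ± 0.18). Forebrain patterning genes included Tcf7l2 (-0.52 ± 0.10) and Gsx2 (1.53 ± 0.40), and Gbx2, a midbrain and hindbrain gene, stood at 0.312 ± 0.107 CPM in wild type and 1.13 ± 0.32 CPM in null. Wnt receptor genes Fzd8 (-0.58 ± 0.13) and Fzd2 (-0.64 ± 0.15), immediate early genes Dusp6 (-0.27 ± 0.08) and Klf4 (-0.58 ± 0.19), and p53 targets Cdkn1a (-0.21 ± 0.07) and Sesn1 (-0.22 ± 0.08) stood lower without passing. With the sample-name term some members of the lists without a call did pass, among them Cdkn1a (-0.30, adjusted p = 0.0321), Egr1 (-0.44, adjusted p = 0.0135), Sox9 (-0.36, adjusted p = 0.0158), Sox10 (-1.10, adjusted p = 0.0231) and Col11a1 (0.44, adjusted p = 0.0288). Interferon genes were split, with Ifi27 at 1.48 ± 0.32 and B2m at -0.36 ± 0.09, and mitotic genes Nusap1 (-0.15 ± 0.06) and Kif23 (-0.12 ± 0.07) did not pass. With edgeR no call was made for markers of microglia (Cd68, 0.43 ± 0.26, and P2ry12, -0.21 ± 0.23), vessels (Tagln, 0.54 ± 0.24, and Emcn, -0.99 ± 0.56) and fibroblasts (Fbln1, -0.54 ± 0.13, and Col1a1, 1.14 ± 0.53). Nor did edgeR call germline genes (Sycp1, 0.75 ± 0.42, and Brdt, 0.48 ± 0.27), Y-linked genes (Ddx3y, -0.20 ± 0.10, and Kdm5d, 0.13 ± 0.08) or olfactory receptor genes (Olfr1317, 0.67 ± 0.26, and Olfr288, 0.56 ± 0.34). Many of these sizes rested on wild type replicates 1 and 2. Under the sample-name term Emcn stood at 2.29, Col1a1 at -0.23, Cd68 at -0.14 and Brdt at -0.15. There Tagln stood at 0.12, Fbln1 at -0.18, Gja1 at -0.16 and Gsx2 at 0.48. Leaving out wild type replicate 3 instead gave -1.33 for Emcn, 1.79 for Col1a1, 0.67 for Cd68 and 0.76 for Brdt. It gave 0.69 for Tagln, -0.68 for Fbln1, -0.87 for Gja1 and 1.98 for Gsx2.

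Camera adjusted p was 0.383 for silencing regulators, 0.84 for matrix genes, astrocytes, microglia, fibroblasts and forebrain genes, 0.192 for midbrain and hindbrain genes, 0.17 for Wnt and 0.0667 for immediate early genes. It was 0.409 for p53, 0.481 for interferon, 0.383 for G2 and M phase, 0.324 for germline, 0.319 for neural stem cell, 0.893 for vessel, 0.993 for Y-linked and 0.642 for olfactory receptor genes. Midbrain and hindbrain genes lay higher without null replicate 1 (adjusted p = 0.00692), and immediate early genes lay lower without wild type replicate 2 (adjusted p = 0.0258) or null replicate 2 (adjusted p = 0.0213), without a filter (adjusted p = 0.0285) and after thinning (adjusted p = 0.0422). With all libraries both lists had an adjusted p = 0.628 with an estimated correlation, which was not computed for these 5 settings. Erythroid, vomeronasal and Rhox lists held 1 tested gene each, Alas2 (0.49 ± 0.29), Vmn2r29 (0.77 ± 0.30) and Rhox5 (-0.20 ± 0.44). Under the sample-name term astrocyte markers (adjusted p = 7.12e-06) and immediate early genes (adjusted p = 0.0156) lay lower in null. Both calls were lost there, at an adjusted p = 0.556 with an estimated correlation for astrocyte markers and an adjusted p = 0.712 with an estimated correlation for immediate early genes. Median and mean differed in sign for the forebrain (-0.10 and 0.26) and Y-linked lists (0.02 and -0.04). For astrocytes and matrix genes both were positive while camera pointed lower, and for vessels both were negative while camera pointed higher. The mixed fry test, which lets members move either way, gave forebrain genes an adjusted p of 0.0108. Over all 24 lists with tested genes and no call, edgeR called 0 of 342 genes, and 74 had an unadjusted p under 0.05. The limma-voom test called 3 of them, DESeq2 23 and limma-voom with quality weights 174. Without wild type replicate 3 edgeR called 9 astrocyte markers higher and 3 lower, 13 matrix genes higher and 10 lower, 2 silencing regulators higher and 15 lower, and 5 Wnt genes higher and 6 lower. It then called 6 interferon genes higher and 4 lower, 2 p53 genes higher and 8 lower, 3 immediate early genes higher and 6 lower, 1 G2 and M phase gene higher and 7 lower, and 3 forebrain genes higher and 5 lower. Fewer were called there in the lists of fibroblasts (3 higher and 1 lower), midbrain and hindbrain (2 higher), vessels and Y-linked genes (1 higher and 1 lower each), and microglia, germline, olfactory and vomeronasal genes (1 higher each).

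Clustered protocadherins also set the one chromosome that passed as a set. Chromosome 18 held 26 of the rises among 396 tested genes, and camera gave it an adjusted p of 0.0151, or an adjusted p = 0.107 with an estimated correlation. Without its clustered protocadherins the adjusted p was 0.999, and without wild type replicate 3 no chromosome passed (adjusted p = 0.941 for chromosome 18). The X chromosome, with 6 rises (Dcaf12l1, Slitrk4, Nexmif, Dach2, Klhl4 and Map7d2) and 0 falls among 500 tested genes, had an adjusted p of 0.999 and a median log2 fold change of -0.02.

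Called genes lay next to each other more often than chance placed them. There were 25 pairs of neighbouring tested genes called in the same direction, against a mean of 0.341 and a maximum of 4 in 10000 random placements (one-sided permutation p = 0.0001, the smallest they can give). Runs of neighbours covered 9 genes from Pcdha1 to Pcdha10 (chromosome 18, 36.93 to 37.19 Mb), without Pcdha4, which was not among the tested genes. Other runs covered Pcdhb1 to Pcdhb8 (37.26 to 37.36 Mb) and Pcdhb10 to Pcdhb13 (37.41 to 37.45 Mb). On chromosome 7, A330076H08Rik and Ndn were neighbours, and so were Mkrn3 and Peg12 (62.42 to 62.46 Mb). Without the clustered protocadherins 5 pairs remained (mean by chance 0.131, permutation p = 0.0001). The count was 8 or 15 pairs without wild type replicate 1 or 2, and 7, 12 or 8 without null replicate 1, 2 or 3, where chance gave means of 0.056 to 0.11. Without wild type replicate 3 there were 1331 pairs among 5559 called genes, where chance gave a mean of 1104 and a maximum of 1175, a far smaller relative excess.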

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

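Smchd1 kept its fall under all 20 alternatives, with log2 fold changes from -3.16 to -2.96. Of the 25 other named genes called, 12 passed under every alternative run, including Ndn, Peg12, Pcdha6, Pcdha8, Pcdhb4 and Pcdhb22; 13 lost their call under at least 1, and 0 changed sign. Counts of changed genes moved with the setting, and the causes were not tested. DESeq2 called 398 genes (177 higher, 221 lower), limma-voom 127 (23 lower), and limma-voom with sample quality weights 5168 (2700 higher, 2468 lower), including all 72 rises and 10 falls. Without a filter 222 were called (163 higher, 59 lower). The term for the range of sample names gave 186 (109 lower), and the libraries named 11 to 14 alone, an alternative added after the data were seen, 376 (126 higher, 250 lower). Without genes above 1% of a library, and with thinning, also added afterwards, 6 genes fell. Leaving out each library in turn gave 30 to 5676 changed genes, 29 to 2857 higher and 1 to 2819 lower; the top of each range came without wild type replicate 3. The replicate block called 54 genes (6 lower), of which 46 rises and 2 falls were shared. Same-numbered libraries did not deviate together (r = -0.006, 0.027 and -0.041 across genes), and not every library correlated best with its own number, so the numbers were not taken to pair the samples.

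Camera called 7 lists, 4 to 8 when a library was left out, with 4 both without wild type replicate 1 and without replicate 2. With an estimated correlation it called 0, and the alpha and beta protocadherins both had an adjusted p = 0.0958. The fry test for a shared direction called 2. With the sample-name term, then with names 11 to 14 alone, 3 lists turned: oligodendrocyte lineage (adjusted p = 0.00204 and 0.00233), S phase (0.147 and 0.154) and cohesin, condensin and CTCF (0.569 and 0.569). Chromosome sets that passed numbered 0 with an estimated correlation and 0 to 1 when a library was left out. Depth limited wild type replicate 3 most, with an effective depth of 10.1 M counts.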

Other observations

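The correlations along the protocadherin clusters, the 3 regions named below, the counts of zinc finger and X-linked genes and the test of the label of wild type replicate 3 were chosen after the results were seen. Fold changes fell along the protocadherin clusters, from the first genes to the last. Across the 13 alpha genes, which are not independent replicates, the Spearman correlation of gene start with log2 fold change was -0.94 (adjusted permutation p = 0.00016), and across the 22 beta genes it was -0.79 (adjusted permutation p = 0.00016), among 12 relations computed. Adding the sample-name term gave -0.88 and -0.72. In the gamma cluster, where no gene was called, the correlation was -0.44 without the term (adjusted permutation p = 0.0624) and -0.55 with it (adjusted permutation p = 0.0145). In the alpha and beta clusters the wild type level carried the gradient. Mean wild type CPM rose with position (0.86 for alpha, 0.77 for beta), while mean null CPM gave -0.04 and 0.42 (adjusted permutation p = 0.892 and 0.0753). In the gamma cluster neither level was ordered, at 0.09 for wild type and -0.14 for null (adjusted permutation p = 0.749 and 0.634). Genes at the start of the alpha and beta clusters were near 0 in wild type cells, and in null cells the level was not ordered in the alpha cluster.

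Genes that rose also gathered in smaller regions. On chromosome 4, between 145 and 148 Mb, 5 of 21 tested genes rose: the pseudogene Znf41-ps (log2 fold change 1.46 ± 0.08, adjusted p = 0.000202) and the zinc finger genes Zfp992 (1.66 ± 0.12), Zfp993 (1.43 ± 0.15), Zfp991 (1.12 ± 0.13) and Zfp979 (1.65 ± 0.19), all 5 also with the sample-name term. These genes are close relatives, and reads could be shared between them as in Zfp992 and Zfp993, which are neighbours. On chromosome 12, between 18 and 25 Mb, 6 of 26 tested genes rose, each with a predicted or clone name, among them 1700030C10Rik (4.34 ± 0.34, adjusted p = 0.000891) and 5730507C01Rik (3.45 ± 0.29). Of these 6, Gm5953 (adjusted p = 0.0721), 6030426L16Rik (adjusted p = 0.104) and Gm4425 (adjusted p = 0.268) lost their calls with the sample-name term. On chromosome 7, between 61 and 63 Mb, 4 of 6 tested genes rose, Ndn, Mkrn3, Peg12 and A330076H08Rik. Genes with a numbered Zfp symbol made up 5 of the rises among 335 tested (odds ratio 3.12, 95% interval 0.975 to 7.72, Fisher's exact p = 0.0274). All of these except Zfp976 lie in the chromosome 4 region above. Fisher's test takes genes as independent, so its p and interval overstate what these neighbours show. On the X chromosome 6 of 500 tested genes rose, against 63 of 13247 on autosomes (odds ratio 2.54, 95% interval 0.894 to 5.89, Fisher's exact p = 0.0392), among them Klhl4 (2.56 ± 0.20) and Dach2 (2.34 ± 0.23). Both intervals include 1, so neither excess is firm.

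The first principal component did not separate the genotypes: it set wild type replicates 1 and 2 apart from the 4 libraries named 11 to 14. The counts taken by a few records do not by themselves account for this. Without the records above 1% of any library, at equal totals, wild type replicate 3 still lay with the null libraries on component 1. On that component alone it lay 38.2 times farther from the other wild type libraries than from the null libraries. On component 2, with all records kept, it lay apart from the null libraries (32.6 against -12.1 to -9.46). The records above 1% together took 58.3% of wild type replicate 3 and 8.28% to 11.7% of the null libraries. They took 7.31% and 5.84% of wild type replicates 1 and 2, so their share followed the split. Leaving them out removes only their counts, so it cannot exclude another difference between the libraries that goes with that share. A wrong label is argued against by Smchd1, which stood in wild type replicate 3 at 87.4% of its mean in wild type replicates 1 and 2. Differences that share no library, wild type replicate 3 minus replicate 1 and the null mean minus wild type replicate 2, correlated across genes (r = 0.655, and 0.634 with the replicates exchanged). The split on component 1 already implies such a correlation. The correlation therefore cannot tell a batch shared by the libraries named 11 to 14 from another cause of the split. Such a batch and the genotype cannot be told apart in the comparison of null with wild type replicates 1 and 2. A difference between embryos or litters stays open as untested. With genotype alone, with the sample-name term, with the block and without wild type replicate 3, 43 rises and 2 falls passed alike. Of these rises, 20 were clustered protocadherins. The fit without wild type replicate 3 is that same comparison and kept all 72 rises and 10 falls, so it is no check on the split. Only the sample-name term addresses the split, and it rests on wild type replicate 3 as the only wild type library named among 11 to 14.

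Only 1 of the 10 splits of the 6 libraries into 3 and 3 gave as many called genes as the real one, the real split itself, with 82 genes against 0 at most in the others. At an unadjusted p under 0.05 the other splits gave 37 to 2070 genes, and they gave 0 with limma-voom, up to 103 with DESeq2 and up to 4872 with limma-voom and quality weights. The splits that kept wild type replicates 1 and 2 together gave 4250 or more with that last tool, which points to a structure of the samples other than genotype. With 10 splits a share under 0.05 is out of reach.

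Neighbouring genes that rose together could come from reads shared between paralogs in the protocadherin and zinc finger clusters. Against this as the whole cause, 2 neighbouring pairs had symbols of different families once genes with predicted or clone names were left out, Mkrn3 with Peg12 and Dach2 with Klhl4, against a mean of 0.246 by chance (one-sided permutation p = 0.0233). Under the sample-name term there were 3 such pairs (permutation p = 0.0783). Within each protocadherin cluster, sharing of reads stays open.

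MommeD1 lies on chromosome 17, and strain variants carried along with the allele could change nearby genes. Of 169 tested genes within 20 Mb of Smchd1, edgeR called 0, which allows a share of up to 1.78%, against 77 of 13598 elsewhere (Fisher's exact odds ratio 0, upper 95% bound 3.97). Among the 169, 39 had an unadjusted p under 0.05, limma-voom called 0, DESeq2 7 and limma-voom with quality weights 71. Over all 14207 tested genes these counts were 2642, 127, 398 and 5168, so they do not single out the region. With the sample-name term edgeR called 1 of the 169, against 177 of 13598 elsewhere. The bound is too wide to exclude an effect of linked variants on these genes, so the 2 cannot be told apart there.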
